A study of Drosophila melanogaster with 30 samples.

How the data were processed

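The series holds 30 Affymetrix expression arrays of Drosophila melanogaster prothoracic leg imaginal discs, the larval epithelial sacs that form the adult forelegs. Per the labels, the discs came from male larvae aged 100 h at 25 °C. Biotin-labelled cRNA was made from total RNA by a two-cycle amplification, which is used for small tissue samples. Per the submitters' processing notes, RMA and limma were used, and their roles, settings and versions are not given in the sources used here. The deposited value table holds log2 expression values for 18952 probe sets on the 30 arrays. A further 2 deposited tables hold log2 differences between group means and an adjusted p-value per probe set, for probe sets with an adjusted p-value under 0.001 over 4 cut comparisons (1480 probe sets) or over 4 culture comparisons (3018 probe sets). With limma's moderated F-test on the deposited values and the same threshold, 1489 and 3018 probe sets passed. All listed probe sets were among them, and the 9 unlisted ones were control probe sets.

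The deposited log2 values have no absolute level. Each probe set averages 0 within each of 3 separate sets of arrays, which hold 15, 6 and 9 arrays and are unions of whole groups. The largest absolute mean of a probe set within a set was 8.2e-09. No label records this step. The first set held the cut A1/4 groups of both times and the 3 uncut P3/4 groups. The second held the cut P3/4 and uncut A1/4 groups at 12 h. The third held the cut P3/4 group at 24 h and the uncut A1/4 groups at 0 and 24 h. A region effect of 1 and a cut response of opposite sign in the pieces gave the same centred value in each group. A difference between groups of different sets lost the difference between the set means. Of the 13 comparisons fixed before the data were examined, 10 cross sets and 3 do not. A uniform effect was passed through the same centring to measure what each comparison returns. An effect of 1 log2 unit of cutting came back as 1.1 and 0.90 in A1/4 and P3/4 at 12 h and as 0.93 and 1.07 at 24 h. A culture effect of 1 entered those 4 comparisons as 0.20, -0.20, -0.13 and 0.13, and a region effect of 1 as 0.10, -0.10, 0.27 and -0.27. Culture of A1/4 for 12 h returned 0.67 of the culture effect, and the uncultured region comparison 0.73 of the region effect. For this reason 6 comparisons in which the set means cancel were added after the data were seen. These are the cut response averaged over both regions at 12 h and at 24 h, the difference between these times, cut discs at 24 h against uncultured discs averaged over both regions, and A1/4 against P3/4 averaged over cut and uncut cultured discs at each time.

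A linear model with 1 mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with 20 residual degrees of freedom. Variances were moderated by empirical Bayes with a prior of 5.26 degrees of freedom. The 183 control probe sets were left out, and p-values of the other 18769 were adjusted by the Benjamini-Hochberg method per comparison with a threshold of 0.05. All tests were two-sided. Errors are standard errors (SE) of the fit unless called SD. The fit takes group means as independent, but the centring ties the means of groups in a set. In the 10 comparisons that cross sets, SE, p-values and counts of calls are therefore not calibrated. The number of arrays, 3 per group, limits the precision. The labels call the replicates biological, and no pair of replicates held identical values.

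Gene names came from the 2 deposited tables of comparisons and were updated through the gene table of the assembly Release 6 plus ISO1 MT, used for names only. They cover 3323 probe sets and 3170 genes, or 17.7% of the tested probe sets, and 15446 tested probe sets are without a name here. Of the names, 2632 equalled a current symbol, 648 were updated through a synonym, and 33 with several matches and 10 with no match were kept as deposited. Because only probe sets of those 2 tables have names, every named gene was selected by the authors on these same samples. For a gene with several probe sets, the planned choice by highest mean was impossible after centring. The probe set with the most specific suffix (plain, then a, s and x) and the lowest number stood for the gene. Genomic positions are not given because no source used here states the build.

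Gene lists fixed before the data were examined comprised 25 pathway lists and 9 lists of cell type markers. List members could be counted only where they were named, so counts below are shares of named members and not of whole pathways. Named were 3 of 19 Wnt genes, 7 of 16 Notch, 5 of 19 leg patterning, 3 of 13 Dpp and 3 of 15 EGFR and Ras genes. The same held for 51 of 90 oxidative phosphorylation genes, 18 of 94 cytosolic ribosomal protein genes and 11 of 29 DNA replication genes. Members without a name were not counted, whatever their values. Lists with at least 3 named genes were tested against the other named genes with limma's camera at a preset correlation of 0.01, with a second test at an estimated correlation, and p-values were adjusted over the lists of each kind. Members called are counted over all probe sets and, separately, adjusted over the list alone. Since all named genes were selected on these samples, neither count is independent evidence of a list's direction. For the 4 cut comparisons the 8 largest rises and 8 largest falls among called genes whose 3 cut and 3 uncut arrays did not overlap were to be named, with up to 4 members of each described list by adjusted p and a fixed panel of wounding genes. For culture and region comparisons and for differences of responses, 5 in each direction were taken. The added comparisons used the same rule, with overlap checked within each region or treatment. Except in the 3 culture comparisons within a set, the groups checked for overlap lay in different centred sets. Whether their arrays overlapped therefore depended on the set means, and the check does not show separation within a set. Further members of lists were named after their values were seen. The alternatives were quantile normalization or median centring of the arrays, robust empirical Bayes, array weights, other thresholds, a fit of the compared groups alone, named genes alone, a replicate block and leaving out each array. A filter on dim probe sets and a variance trend could not be run because centring removed the levels.

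The steps were tested on simulated data with 18769 probe sets, 200 of them changed, and the same 3-set centring. For the cut response averaged over both regions at 12 h, 95.5% of 67 probe sets changed 1.5-fold were called with the right sign, 98.5% of 67 changed 2-fold and 100% of 66 changed 3-fold. Of all calls, 6.67% were unchanged probe sets. At 24 h the same values were 94.0%, 98.5%, 100% and 5.34%. For the cut response in A1/4 at 12 h, 89.6%, 97.0% and 100% were called and 0.521% of calls were unchanged probe sets. The simulated changes were cut effects alike in both pieces, without culture or region effects. The last share therefore does not measure false calls that such effects cause in a comparison that crosses sets. In a list simulation on the 3170 named genes for the 12 h mean of both regions, a list shifted by 0.8 log2 units was called (adjusted p = 6.5e-31) and 0 other lists were called. The simulated genes varied independently of each other. The list simulation therefore does not measure false list calls where genes of a list vary together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.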

Results

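The series measured gene expression in regenerating leg discs. Prothoracic leg discs were cut into an anterior piece of 1/4 of the disc (A1/4) or a posterior piece of 3/4 (P3/4) and kept in the abdomen of adult female flies for 12 or 24 h, a host culture in which disc pieces survive and grow. Cut samples were the isolated GFP-positive cells of these pieces, which the genotype marks by descent from cells with activity of a GAL4 driver in puckered (puc), a target of JNK signalling. Control samples were the corresponding regions dissected from uncut discs, cultured for 12 or 24 h in the same way or not cultured. The cut and uncut samples therefore differ in how their cells were selected as well as in the cut, and puc, which chose the cells, is not a finding. Each difference between cut and uncut samples below, of any gene, holds this selection too, and the arrays cannot separate it from the cut. The design has 10 groups of 3 arrays. The 3 questions that it poses are how cut discs differ from uncut discs cultured for the same time, what culture alone does, and whether both pieces respond alike.

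Values are differences of centred log2 values, and the text leads with the comparisons in which the separate centring of 3 sets of arrays cancels. The 6 that average regions or treatments were chosen after the data were seen. Array medians lay between -0.04 and 0.04, and the SD of the difference between replicates ranged from 0.18 to 0.36 within groups.

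Culture alone changed many genes. In uncut P3/4 regions after 24 h, the cuticle protein genes Cpr100A and Lcp65Ad were 38.3-fold and 22.7-fold higher than without culture (log2 5.26 ± 0.80 SE and 4.51 ± 0.64, n = 3 per group). Thor, which encodes a repressor of translation, rose 12.9-fold, and ImpE2, an ecdysone-inducible gene of imaginal discs, was 15.5-fold lower. In A1/4 at 24 h, Cpr100A rose 86.8-fold, Lcp65Ad 31.1-fold and the chitin deacetylase gene Cda5 21.6-fold, while the cuticle protein gene Cpr49Ac was 32.0-fold and ImpE2 21.6-fold lower. In P3/4 at 12 h, ImpE2 was already 32.3-fold and wbl, a gene of a chaperone-like protein of the endoplasmic reticulum, 15.7-fold lower, and Lcp65Ad was 18.2-fold higher. The other largest rises of named genes were CG8620, CG11893, CG13215 and CG6142 in P3/4 at 12 h, with log2 values of 6.38, 4.92, 4.20 and 3.90, CG6142 and CG4404 in P3/4 at 24 h (4.53 and 3.68) and Ude and CG6142 in A1/4 at 24 h (4.46 and 4.36).

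Genes of energy production, DNA replication and ribosome assembly fell together in culture. Of 51 named genes of oxidative phosphorylation, 44 fell in P3/4 at 12 h, 47 in P3/4 at 24 h and 51 in A1/4 at 24 h, and 0 rose (47, 48 and 51 adjusted over the list alone). These lists hold only genes named in the authors' tables, chosen on these samples, so no count over the list alone is independent evidence of direction. Their medians were -0.56, -0.58 and -0.86. At 24 h in P3/4, examples were COX8 (-1.32), Cyt-c-p (-1.18) and COX7C (-0.99), subunits or carriers of the respiratory chain. Of 11 DNA replication genes, 11, 10 and 11 fell in the same order of comparisons, and 11 in each adjusted over the list alone. They included the primase subunit gene Prim1 (-1.70 in P3/4 at 24 h) and the helicase gene Mcm7 (-1.27). Of 19 ribosome biogenesis genes, 18, 17 and 17 fell and 1, Non1, rose (18 falls and 1 rise in each adjusted over the list alone), with Nopp140 (-1.01) and nop5 (-1.14) in P3/4 at 24 h. All 3 lists were called by camera in these 3 comparisons, with the highest adjusted p for DNA replication in P3/4 at 12 h (0.00221). With an estimated correlation every one of these calls was lost, with adjusted p = 0.618 for each list in P3/4 at 12 h, adjusted p = 0.766 in P3/4 at 24 h and, in A1/4 at 24 h, adjusted p = 0.707 for oxidative phosphorylation and DNA replication and 0.729 for ribosome biogenesis.

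Genes of apoptosis and DNA damage moved the other way. Of 10 named members, 10 rose in P3/4 at 12 h, 9 in P3/4 at 24 h and 9 in A1/4 at 24 h, and 0 fell, with the same counts adjusted over the list alone. At 24 h in P3/4 the Bcl-2 family gene Buffy rose by 1.89, Irbp, a Ku subunit of DNA end joining, by 1.43 and the stress response transcription factor gene Xrp1 by 1.34. Camera called the list in P3/4 at 12 h and 24 h (adjusted p = 0.0146 and 0.0409) but not in A1/4 at 24 h (0.153). With an estimated correlation the values were adjusted p = 0.618 and 0.766. Of 16 genes of the ecdysone response and developmental timing, 4 rose and 8 fell in P3/4 at 12 h, 5 and 8 in P3/4 at 24 h, and 4 and 8 in A1/4 at 24 h (4 and 9, 5 and 8, and 4 and 8 adjusted over the list alone). In P3/4 at 24 h the nuclear receptor gene ftz-f1 rose by 2.08, and ImpE3 (-2.47) fell.

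Some measures of RNA quality and, separately, of hybridisation differed after culture. The difference between 3′ and 5′ control probe sets of actin was higher after culture by 0.57 in P3/4 at 12 h, 0.67 in P3/4 at 24 h (each ± 0.23 SE) and 1.76 ± 0.23 in A1/4 at 24 h, and the hybridisation controls were lower by -0.75 ± 0.20 log2 units in A1/4 at 24 h. For GAPDH the 3′ to 5′ difference was 1.39 ± 0.30 in A1/4 at 24 h, but 0.14 and 0.21 (each ± 0.30) in P3/4 at 12 and 24 h, where the hybridisation controls were at 0.07 and -0.06 (each ± 0.20). Yp1, a yolk protein gene of adult females and the 1 named marker of the host, was 3.16 log2 units higher in A1/4 at 24 h (called), against 0.29 and 0.41 in P3/4 at 12 and 24 h (not called). Of 5 haemocyte markers, 4 rose in A1/4 at 24 h, 2 in P3/4 at 24 h and 0 in P3/4 at 12 h (4, 4 and 0 adjusted over the list alone), and their median in P3/4 at 12 h, 0.39, turned to -0.23 after quantile normalization. Over all probe sets, culture gave 1963 rises and 1832 falls in P3/4 at 12 h, 2731 and 1794 in P3/4 at 24 h, and 2632 and 3388 in A1/4 at 24 h. In A1/4 at 24 h quantile normalization lowered the count of calls from 6020 to 3455, and the share of rises, 43.7%, was 50.0% after it and 53.2% after median centring, so falls did not outnumber rises under every scaling. In P3/4 at 12 h the share was 51.7%, and 49.2% after quantile normalization. In A1/4 at 12 h, where 0.67 of a culture effect is returned, 1784 probe sets rose and 1181 fell, and 36 of 51 oxidative phosphorylation genes fell (44 adjusted over the list alone). This count of 2965 calls was 1910 after quantile normalization.

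At 12 h, TotM, Ilp8 and upd were among the largest rises in cut discs over uncut discs cultured for the same time. In the mean of both regions (6 cut and 6 uncut arrays), TotM, a secreted protein gene, was 7.39-fold higher (log2 2.89 ± 0.42 SE). This TotM value averages unequal differences within the centred sets. In the first set, cut A1/4 arrays lay at 3.33 to 4.51 and uncut P3/4 arrays no higher than -0.76. In the second set, cut P3/4 arrays (-0.16 to 1.25) overlapped uncut A1/4 arrays (-0.89 to -0.06). Both differences also hold the difference between regions, so the TotM response cannot be split by region. In the same mean, Ilp8, whose relaxin-like peptide is released by damaged discs and delays pupariation, rose 5.91-fold (2.56 ± 0.15). The gene upd, encoding a JAK/STAT ligand, rose 4.53-fold (2.18 ± 0.14). The muscle giant protein gene bt rose 4.37-fold and NimC4, a receptor gene for uptake of dying cells, 3.34-fold. Further large rises were CG5002 (2.06), acs (1.87) and CG5958 (1.76). Among the largest falls, CG13857 was 6.20-fold lower, ana, encoding a secreted protein of glia that restrains neuroblast division, 4.71-fold, and magu, encoding a secreted protein that modulates BMP signalling, 3.82-fold. The others were lncRNA:CR33938 (-1.97), Kots (-1.68), CG9008 (-1.67), Muc91C (-1.56) and CG15905 (-1.52).

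Signalling genes of the 12 h response went both ways. Of 8 JAK/STAT genes, 5 rose and 1 fell (the same adjusted over the list alone). The rises were TotM, upd, the ligand gene upd3 (0.55), the phosphatase gene Ptp61F (0.49) and the transcription factor gene chinmo (0.58), whose call ended without cut A1/4 replicate 1 (0.46), cut P3/4 replicate 1 (0.51) or uncut A1/4 replicate 3 (0.53). The kinase gene hop fell by 0.33, and the feedback inhibitor gene Socs36E did not pass (0.16, adjusted p = 0.187). Camera called the list (adjusted p = 0.0117), against adjusted p = 0.339 with an estimated correlation. Since puc, a JNK target, chose the cut cells, changes of other JNK genes cannot be told apart from this selection. The other cut responses, those of Ilp8, upd and patterning genes included, share this limit, as selected cells were compared with whole regions. Of 11 genes of JNK signalling and its targets, 4 rose and 3 fell (4 and 3 adjusted over the list alone). The rises were Ets21C, an ETS transcription factor gene (1.46), scaf (1.19), the growth factor gene Pvf1 (1.11) and the matrix metalloproteinase gene Mmp1, and the falls were Gadd45 (-0.82), kay (-0.48) and egr (-0.45). The other probe sets of egr (-0.33, adjusted p = 0.257) and chinmo (0.54, adjusted p = 0.0912) did not pass. The probe set that stands for Mmp1 gave 0.52 (adjusted p = 0.0352), a call that ended when any 1 of 8 arrays was left out (0.44 to 0.55), and its other 2 probe sets gave 1.48 and 1.74, both called. All 3 named Wnt genes, of 19 on the list, fell (Wnt2 (-1.26), Wnt4 (-0.79) and fz (-0.47)). Of 7 named Notch genes 6 fell, among them the ligand gene Dl (-0.45) and Su(H) (-0.48). All 5 named genes of leg proximodistal patterning fell, among them B-H2 (-1.02) and bab1 (-0.71). The fall of ap (-1.02) was not seen in its other probe set (-0.028, adjusted p = 0.870). These counts were the same adjusted over the list alone. Camera called Wnt and Notch (adjusted p = 0.0286 for each), against adjusted p = 0.339 for each with an estimated correlation, and did not call leg patterning (adjusted p = 0.0583). After quantile normalization B-H2, bab1 and the Dpp target gene bi were no longer called at 12 h.

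Housekeeping groups at 12 h moved in part. Of 51 oxidative phosphorylation genes, 21 rose and 0 fell (25 adjusted over the list alone), with Cyt-c-p at 0.79. Of 19 ribosome biogenesis genes, 15 rose and 1 fell (17 and 1 adjusted over the list alone), and of 11 DNA replication genes 4 rose (5 adjusted over the list alone). Of 18 cytosolic ribosomal protein genes, 14 fell and 2 rose (14 and 2 adjusted over the list alone), with RpS9 (-1.22) and RpL3 (-0.85) lower and RpS5b (0.90) and RpLP0-like (0.61) higher, and -0.39 in the other probe set of RpS9. Of 5 glycolysis genes, 3 fell (Pfk (-0.71), Ald (-0.58) and Pgi (-0.48), 3 adjusted over the list alone, and -0.33 in the other probe set of Ald). Adjusted p from camera were 9.8e-07, 2.0e-05, 0.0286, 0.00173 and 0.0413 in this order. With an estimated correlation they were adjusted p = 0.412, 0.339, 0.531, 0.339 and 0.339. Of 10 genes of antimicrobial peptides and immune recognition, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with the recognition protein gene PGRP-SA up by 1.26 and the NF-kappaB gene Rel as the fall (-0.25) (camera adjusted p = 0.0117, and adjusted p = 0.339 with an estimated correlation). Alongside, 3 of 5 haemocyte markers rose (Hml (1.05), eater (0.90) and NimC1 (0.72)) and 1, ush, fell (-0.55), or 4 and 1 adjusted over the list alone. All 5 myoblast markers fell (twi (-0.69), Mef2 (-0.67), zfh1 (-0.63), Him (-0.54) and htl (-0.53)), 5 also adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.258 with an estimated correlation).

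The genes of apoptosis and DNA damage did not rise together in cut against uncut cultured discs. Of 10, 1 rose and 4 fell at 12 h (1 and 4 adjusted over the list alone), with Corp at 0.57 and Buffy (-0.59), Dcp-1 (-0.37) and Debcl (-0.34) among the falls, and 1 rose and 1 fell at 24 h (1 and 1), Corp (0.73) and Buffy (-0.47). Without 1 array, the call of Corp at 12 h was lost for any 1 of 4 arrays, that of Debcl for 2 and that of Buffy at 24 h for 5. Camera did not call the list (adjusted p = 0.436 and 0.285). Of 16 ecdysone and timing genes, 2 rose and 6 fell at 12 h and 2 rose and 6 fell at 24 h (2 and 6, and 3 and 8 adjusted over the list alone).

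Over all probe sets at 12 h, 1223 rose and 1877 fell. Taken by region, 592 rose and 1068 fell in A1/4, and 377 and 570 in P3/4. Ilp8 rose by 3.16 in A1/4 and 1.97 in P3/4, and upd by 2.62 and 1.74, values that hold the returned share of culture and region effects given with the processing. The centring also removes most of a true difference between the pieces, so the size of the response in A1/4 against P3/4 cannot be read from them. The A1/4 count fell to 839 without cut replicate 3. The P3/4 count fell to 627, 554 and 454 without cut replicates 1, 2 and 3 and to 393 and 397 without uncut replicates 2 and 3, and was 2180 after quantile normalization and 2589 with array weights. The count of 3100 for the mean of both regions was 4653 with array weights.

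**Figure D1:**
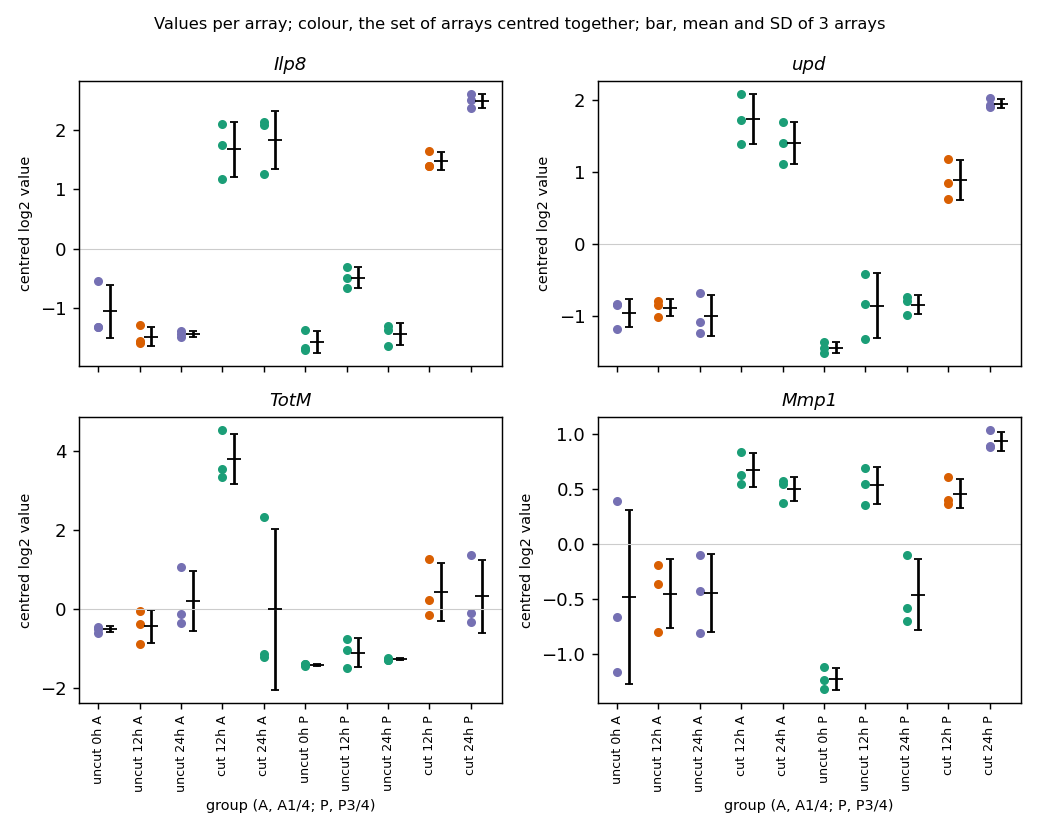
Centred log2 values (y axis) of Ilp8, upd, TotM and Mmp1 on each of the 30 arrays by group (x axis), where colours mark the arrays centred together and bars give the mean and SD of 3 arrays. The 12 cut arrays lie between 1.18 and 2.60 for Ilp8 and the 18 uncut arrays between -1.70 and -0.31, and TotM is high on 1 of 3 cut A1/4 arrays at 24 h (2.33).

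At 24 h, Ilp8, CG17108 and upd had the largest rises of named genes. In the mean of both regions, Ilp8 was 12.1-fold higher in cut than in uncut cultured discs (log2 3.60 ± 0.15 SE, 6 cut and 6 uncut arrays), CG17108 8.80-fold (3.14 ± 0.39) and upd 6.04-fold (2.59 ± 0.14). The receptor gene mthl2 rose 4.28-fold, the tyrosine decarboxylase gene Tdc1 3.84-fold and Miox, encoding an inositol oxygenase, 3.56-fold. Other large rises were CG17124 (1.84) and CG14984 (1.76). Large falls were CG13857 at 6.27-fold lower, the serpin gene Spn43Aa at 5.15-fold, ana at 5.0-fold, the transcription factor gene lov at 4.47-fold and the glucose dehydrogenase gene Gld at 3.84-fold, with CG32055 (-2.21), Muc91C (-2.05) and CG15212 (-1.93).

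Of the 51 oxidative phosphorylation genes, 50 rose at 24 h and 0 fell (51 and 0 adjusted over the list alone), with Cyt-c-p (1.27), COX8 (0.88) and COX5B (0.87). Of 11 DNA replication genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with Prim1 (1.18), Mcm7 (0.75) and dup (0.76). Of 19 ribosome biogenesis genes, 18 rose and Non1 fell (the same adjusted over the list alone), with Nop60B (1.09) and nop5 (0.91). Of 12 genes of oxidative stress and detoxification, 9 rose and 0 fell (10 and 0 adjusted over the list alone), among them the glutathione transferase genes GstE6 (2.24), GstE5 (1.49) and GstE3 (1.42) and the mitochondrial dismutase gene Sod2 (0.41). Adjusted p from camera were 2.7e-14, 6.1e-04, 1.2e-04 and 0.0183. With an estimated correlation they were adjusted p = 0.286, 0.286, 0.314 and 0.286. At 12 h 2 rose and 0 fell of the 12 (2 and 0 adjusted over the list alone). Of 5 glycolysis genes, 4 fell at 24 h, among them Pfk (-0.87), Pgi (-0.41) and Ald (-0.41), and Ldh rose by 1.29 (1 and 4 for rises and falls adjusted over the list alone), and camera did not call the list (adjusted p = 0.0995). Of 18 cytosolic ribosomal protein genes, 3 rose and 2 fell at 24 h (3 and 2), and of 7 Notch genes 0 rose and 4 fell (0 and 4). The hybridisation controls were 0.33 ± 0.14 SE higher in cut discs at 24 h, and the actin 3′ to 5′ difference was -0.28 ± 0.16.

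Of the 10 immune genes, 8 rose at 24 h and 0 fell, also adjusted over the list alone. PGRP-SA rose by 1.69 and the antimicrobial peptide genes CecB, Drs, AttD, AttA and Mtk by 1.28, 1.13, 0.93, 0.92 and 0.90 (camera adjusted p = 0.0226, and adjusted p = 0.286 with an estimated correlation). In the same arrays 4 of 5 haemocyte markers rose (Sr-CI (1.44), eater (1.42), Hml (1.30) and NimC1 (1.21)) and 3 of 5 myoblast markers fell (Him (-0.49), Mef2 (-0.49) and zfh1 (-0.42)), with 4 and 3 adjusted over the list alone. Of the 11 JNK genes, under the same limit from the selection by puc, 6 rose and 1 fell (6 and 1 adjusted over the list alone). Pvf1, Ets21C, Mmp1 and scaf rose by 1.31, 1.18, 1.17 and 1.16 (1.56 and 1.84 for the other 2 probe sets of Mmp1), and the TNF ligand gene egr fell by 0.85 (camera adjusted p = 0.165). The transcription factor gene Atf3 did not pass (-0.07, adjusted p = 0.824). Of the 8 JAK/STAT genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with chinmo (0.71), Socs36E (0.30) and upd3 (0.29) beside upd, and hop at -0.21 (camera adjusted p = 0.131). Of 5 leg patterning genes 4 fell (bab1 (-1.23), ap (-1.19), B-H2 (-0.93) and bab2 (-0.60), 4 adjusted over the list alone, and -0.34 in the other probe set of ap), with a camera adjusted p of 0.0226, and adjusted p = 0.286 with an estimated correlation. All 3 named Wnt genes fell again, with Wnt2 (-1.12) and Wnt4 (-0.83). The fall of fz (-0.22) was lost without uncut A1/4 replicate 3 (-0.19) or uncut P3/4 replicate 1 (-0.20) or 3 (-0.20).

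Over all probe sets at 24 h, 1717 rose and 1623 fell, a share of rises of 51.4% that was 46.8% after median centring. By region, 1050 rose and 568 fell in A1/4, and 902 and 946 in P3/4. In P3/4 the share of rises, 48.8%, was 58.0% when fitted on the compared groups alone and 43.7% with array weights, so neither direction prevailed under every setting. Ilp8 rose by 3.26 in A1/4 and 3.93 in P3/4, under the same limits as the values by region at 12 h. The A1/4 count was 1052 without cut replicate 1 and 836 without cut replicate 2, and the P3/4 count was 1055 and 1079 without uncut replicates 1 and 3.

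**Figure D2:**
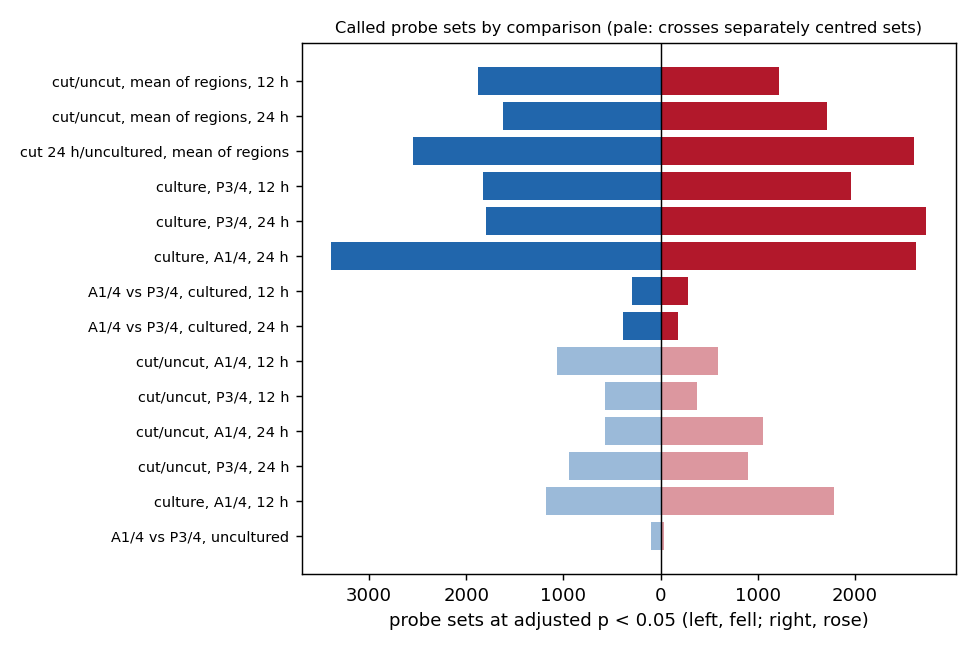
Number of probe sets with an adjusted p under 0.05 (x axis, falls to the left and rises to the right) in 14 comparisons (y axis), with pale bars where the comparison crosses separately centred sets of arrays. Culture of A1/4 for 24 h had 2632 rises and 3388 falls, and A1/4 against P3/4 without culture 39 and 95.

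The cut responses at 12 and 24 h were tested against each other. In the mean of both regions, 54 probe sets were higher at 24 h and 15 lower, and at an unadjusted p under 0.05 the number was 2028. The response of CG14598 was 2.85 ± 0.27 SE higher at 24 h, and those of Miox, the calcium-binding protein gene regucalcin, geko and CG30217 2.0, 1.57, 1.22 and 1.21 higher. The response of Ilp8 rose by a further 1.03 (adjusted p = 0.0266), a call that was lost after quantile normalization and without any 1 of 9 arrays (0.96 to 1.03). The calls of Miox and geko were lost with robust empirical Bayes and without any 1 of 6 arrays (1.87 to 1.96) and 15 arrays (1.09 to 1.25). Responses that were lower at 24 h were those of bt (-1.43 ± 0.20), CG11052 (-1.15), acs (-1.10), the ubiquitin ligase gene gol (-1.03) and CG7201 (-0.91). The changes of Mmp1 (0.64, adjusted p = 0.299) and upd (0.41, 0.434) did not pass. Of 18 cytosolic ribosomal protein genes, 10 had a higher response at 24 h and 0 a lower one (15 and 0 adjusted over the list alone), and of 51 oxidative phosphorylation genes 6 and 0 (32 and 0 adjusted over the list alone). Adjusted p from camera were 1.8e-10 and 7.2e-13, and adjusted p = 0.0864 and 0.639 with an estimated correlation. The median of the ribosome biogenesis genes, 0.08, turned to -0.01 after quantile normalization. The count of 69 calls went down to between 40 and 44 without cut A1/4 replicate 3 at 12 h (42) or 2 at 24 h (40), cut P3/4 replicate 2 (43) or 3 (41) at 12 h, uncut A1/4 replicate 2 at 24 h (44), or uncut P3/4 replicate 2 (40) or 3 (43) at 12 h. It went up to 108 without cut P3/4 replicate 2 at 24 h or uncut P3/4 replicate 2 at 24 h and to 121 without uncut P3/4 replicate 1 at 12 h, and it was 171 after quantile normalization. By region, 300 responses were higher and 103 lower at 24 h in A1/4, and 73 and 16 in P3/4, with a share of a culture effect of -0.33 and 0.33 in these values.

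Cut discs at 24 h were also compared with uncultured discs, in the mean of both regions. mthl2 was 56.3-fold higher (log2 5.82 ± 0.25 SE), Miox 39.8-fold and NimC4 23.7-fold, followed by reb (4.46) and CG4250 (4.44). Ilp8 and upd were 11.1-fold and 7.33-fold higher, chinmo 8.76-fold and Atf3 3.82-fold. ImpE2 was 59.5-fold lower, Spn43Aa 22.5-fold, ImpE3 14.4-fold, CG9416 12.8-fold and Spn100A 11.4-fold. All 10 named immune genes and all 10 named genes of apoptosis and DNA damage rose, each also adjusted over the list alone. PGRP-SA was at 3.81, Drs at 2.45 and Irbp at 1.04. Of 51 oxidative phosphorylation genes 30 fell and 0 rose (32 and 0 adjusted over the list alone), with a median of -0.23. Camera called the immune list (adjusted p = 0.00193) and oxidative phosphorylation (1.9e-05) and not apoptosis (0.0630). With an estimated correlation the first had adjusted p = 0.460 and the second adjusted p = 0.562. In these arrays 4 of 5 haemocyte markers rose, with Hml at 2.59, Yp1 rose by 2.73, and the actin 3′ to 5′ difference was 0.94 ± 0.16 SE higher. Over all probe sets 2614 rose and 2547 fell.

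**Figure D3:**
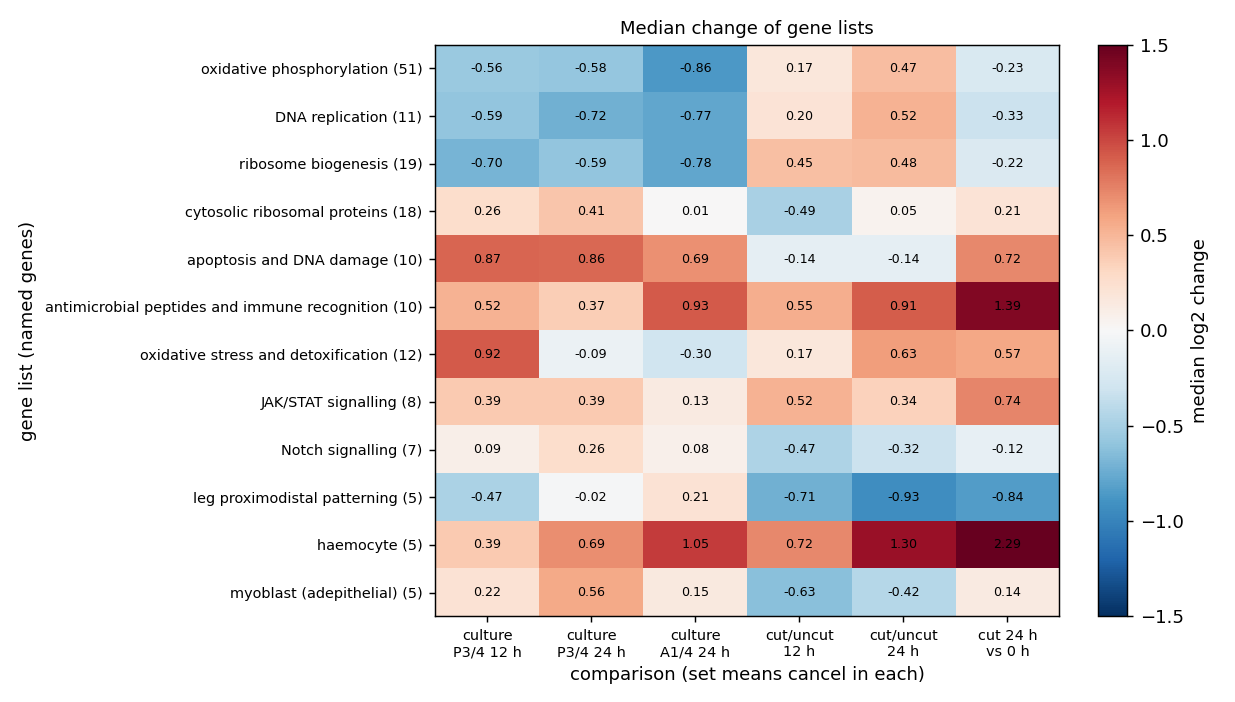
Median log2 change (colour scale and printed values) of 12 gene lists (y axis, with the number of named genes) in 6 comparisons in which the separate centring cancels (x axis). Oxidative phosphorylation was at -0.86 after culture of A1/4 for 24 h and at 0.47 in cut against uncut discs at 24 h, and after quantile normalization 2 culture values changed sign, haemocyte in P3/4 at 12 h (to -0.23) and leg patterning in A1/4 at 24 h (to -0.06), and leg patterning in P3/4 at 24 h changed sign after median centring.

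A1/4 and P3/4 were compared over cut and uncut cultured discs together. After the separate centring, a region difference and a cut response of opposite sign in the pieces give identical values in all 10 groups, so these differences cannot be assigned to region alone. Averaged over cut and uncut cultured discs, Sox21b, a transcription factor gene, was 4.10-fold higher in A1/4 than in P3/4 at 12 h (log2 2.04 ± 0.16 SE, 6 and 6 arrays) and 3.84-fold at 24 h, and CG8483 4.52-fold and 3.55-fold. At 12 h dpr17 (1.18), natalisin (1.10) and tio (1.01) were also higher in A1/4, and at 24 h Ance (1.08), CG15005 (0.97) and Cpr66D (0.89). Gld was 8.56-fold and 7.54-fold lower in A1/4 at 12 and 24 h, and the homeobox gene B-H2 8.25-fold and 6.75-fold, followed by CG32816 (-2.29), sosie (-2.22) and lbl (-2.17) at 12 h and sosie (-2.41), sens-2 (-2.01) and ap (-1.97) at 24 h, with -0.51 in the other probe set of ap. Of 5 leg patterning genes, B-H2, ap and bab1 were lower and tio higher at both times (adjusted over the list alone, 4 lower and 1 higher at 12 h and 3 and 1 at 24 h). Camera called the list (adjusted p = 5.6e-04 and 0.0359), against adjusted p = 0.0884 and 0.537 with an estimated correlation. The glial gene repo was lower in A1/4 (-1.93 at 12 h and -1.62 at 24 h), and of 3 neuron and glia markers 1 was lower at 12 h and 3 at 24 h (2 and 3 adjusted over the list alone). This list kept its call with an estimated correlation (adjusted p = 0.0168 and 0.00620). At 24 h 4 of 10 immune genes were lower in A1/4 (5 adjusted over the list alone), and 1 of 5 haemocyte markers was higher (3 adjusted over the list alone). Camera called both (adjusted p = 0.00750 and 5.1e-04), against adjusted p = 0.537 and 0.0772 with an estimated correlation. At 12 h 278 probe sets were higher and 293 lower in A1/4, against 38.6% higher after median centring and 51.6% after quantile normalization in place of 48.7%, and at 24 h 176 and 390. The 12 h count of 571 was 354 without uncut A1/4 replicate 1, 376 without cut P3/4 replicate 2, and 377 without uncut P3/4 replicate 3. It was 1300 after quantile normalization. Both times shared 51 higher and 139 lower probe sets, against 2.61 and 6.09 for independent lists.

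Without culture, 39 probe sets were higher and 95 lower in A1/4 than in P3/4, in values that return 0.73 of a region effect and as much of a cut response of opposite sign in the pieces, so they need not come from uncultured discs. Sox21b was 4.28-fold higher, CG8483 2.83-fold, and Arc1 (1.39), l(2)34Fc (1.32) and bt (1.11) were also higher, while the other probe set of Arc1 did not pass (0.78, adjusted p = 0.191). The cuticle protein gene Cpr64Aa was 7.63-fold lower, sosie 6.20-fold, the fatty acid elongase gene Elovl7 6.0-fold, B-H2 5.24-fold and CG14598 5.09-fold. The share of higher calls was 29.1%, and 9.38% after quantile normalization, which called 32 probe sets. Of the 10 named genes, 7 lost their call after quantile normalization and 3 without at least 1 array, CG8483 with any 1 of 5 arrays left out (1.10 to 1.68), l(2)34Fc with any 1 of 5 (1.25 to 1.40) and Elovl7 with uncut A1/4 replicate 2 or uncut P3/4 replicate 1 or 2 left out (-2.53 to -2.37). The count of 134 was 306 without uncut A1/4 replicate 1, 66 without uncut A1/4 replicate 3, and 79, 78 and 70 without uncut P3/4 replicates 1, 2 and 3.

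Whether the pieces responded differently to the cut was tested as the difference of the cut response between A1/4 and P3/4. At 12 h 20 probe sets were higher and 19 lower, and at 24 h 13 and 10. At an unadjusted p under 0.05 the numbers were 1040 and 1278. The largest differences were those of CG13215 (4.06), the metallothionein gene MtnA (3.18) and CG14598 (-2.90) at 12 h and of yellow-c (-2.20), sosie (-2.17), PGRP-SA (-2.07) and Sox21b (2.02) at 24 h. The separate centring enters these values with 0.40 of a culture effect at 12 h and 0.53 of a region effect at 24 h. It also removes most of a true difference. A cut response of 1 log2 unit up in A1/4 and 1 down in P3/4 came back as a difference of 0.20 at 12 h and 0.53 at 24 h. A regional difference of the response therefore cannot be read from these values. Of 10 named genes at each time, 8 at 12 h and 9 at 24 h lost their call without at least 1 array. After quantile normalization the share of higher calls at 12 h was 71.8% in place of 51.3%.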

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

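Of the tests in this part, those on responses averaged over both regions were chosen after the result was seen. Differences between the pieces in the cut response passed the test for named genes at both times. At 12 h these were CG13215 (4.06), MtnA (3.18), Lst (2.79), Tig (2.14), CG4267 (1.82), CG14598 (-2.90), nebu (-2.02), CG9896 (-1.74), br (-1.71) and CG32447 (-1.70). At 24 h they were Sox21b (2.02), CG7720 (1.98), CG9896 (1.77), CG32447 (1.65), CG32444 (1.52), yellow-c (-2.20), sosie (-2.17), PGRP-SA (-2.07), CG7432 (-1.71) and CG4267 (-1.68). CG4267, CG9896 and CG32447 had opposite signs at 12 and 24 h. The centring forces this where the uncultured regions differ little, since both differences add up to the uncultured region comparison. Without at least 1 array the call was lost for 8 of 10 genes at 12 h (CG14598 and br kept it) and for 9 of 10 at 24 h (PGRP-SA kept it), after quantile normalization for 4 and 7, and with robust empirical Bayes for 5 and 6. The other probe set of CG4267 did not pass at either time, nor did 1 of 4 of br at 12 h (-1.23, adjusted p = 0.0738).

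Separate centring is a candidate explanation of these regional differences. The differences at 12 and 24 h share no array, but the centring ties them, as they add up to the uncultured region comparison. Their correlation over all probe sets, r = -0.67 across genes, which are not independent replicates, is therefore partly built in. It is no evidence for or against a biological difference. Against the difference predicted from set means of other arrays, the slope over all probe sets was 0.518 at 12 h and 0.697 at 24 h. Of the called probe sets, 94.9% (37 of 39) and 87.0% (20 of 23) had the predicted sign. The centring ties those other arrays to the difference, and an opposed cut response in the pieces would give the same region part. Slopes and signs were thus partly fixed in advance and do not tell centring from a biological difference. The predicted part was at the median 34.1% and 26.2% of the size of the called differences, so a biological difference between the pieces may stay in them and was not separable here. Splits of the arrays between the pieces, the real one included, called as many probe sets as the real 39 in 8 of 100 splits at 12 h (highest other 571) and as many as 23 in 10 of 100 at 24 h (highest other 184), so chance is not excluded. The 571 at 12 h is the region comparison, into which exchanging the pieces in 1 treatment turns the difference, a structure of these samples.

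Differences in the cut response between 24 and 12 h passed for named genes too. In A1/4 these were CG14598 (4.58), Miox (2.52), CG9896 (2.32), regucalcin (2.22), nebu (2.01), TotM (-4.44), CG9701 (-3.09), MtnA (-2.84), Lst (-2.81) and CG5002 (-2.65). In P3/4 they were CG13215 (4.99), GstE6 (4.20), Ddc (4.03), GstE7 (3.95), GstD2 (3.71), CG13305 (-2.55), CG17564 (-2.03), Jhbp2 (-2.0), onecut (-1.76) and FASN3 (-1.72). In the mean of both regions, where centring cancels, they were CG14598 (2.85), Miox (2.0), regucalcin (1.57), geko (1.22), CG30217 (1.21), bt (-1.43), CG11052 (-1.15), acs (-1.10), gol (-1.03) and CG7201 (-0.91). Splits of the arrays between times, the real one included, called as many in 2 of 100 (real 403, highest other 485) in A1/4, 3 of 100 (89 and 146) in P3/4 and 1 of 100 (69 and 33) in the mean, shares under 0.05. These splits mix separately centred sets, so the shares do not exclude chance. The differences in A1/4 and P3/4 also hold -0.33 and 0.33 of a culture effect through the centring, which stays open as their explanation. Without at least 1 array the call was lost for 2 of 10 genes in A1/4, Miox and CG9701, and for 7 of 10 in P3/4, where CG13215, GstE7 and GstD2 kept it. With robust empirical Bayes it was lost for 1 gene in A1/4 and 5 in P3/4, and after quantile normalization for 0 and 2.

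Outside the tested probe sets, 5 of 100 control probe sets of the array's fly series were at least 2-fold higher in cut discs at 24 h than in uncultured discs in the mean of both regions. Numbered by size, they were higher by 6.13, 5.61, 4.81, 4.74 and 1.53 log2 units (SE from 0.17 to 0.20). Against uncut cultured discs at 24 h they were higher by 1.47, 1.13, 1.04, 1.01 and 1.00. Culture of uncut discs alone raised the first of them by 4.92 in P3/4 at 12 h, 4.80 in P3/4 at 24 h and 4.53 in A1/4 at 24 h, and the fourth by 3.96, 4.01 and 3.44. The fifth was higher by 1.18 and 0.82 in P3/4 and did not pass in A1/4 (0.24, adjusted p = 0.465). No explanation was tested.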

How the results depend on the processing

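Alternatives for the region means, robust empirical Bayes without a trend and the suffix choice of probe sets were added after the data were seen. Of 11394 alternative values of 630 results for 220 named genes, 10289 kept direction and side of the threshold, 1083 kept direction and lost the call, 11 gained it and 11 changed sign. The 11 sign changes were all in values without a call: Atf3 in cut A1/4 at 12 h (-0.10 without cut replicate 1 and -0.03 without uncut replicate 3, range over arrays -0.10 to 0.14), Mmp1 in cut P3/4 at 12 h (0.15 after quantile normalization and 0.0052 without uncut replicate 2, range -0.16 to 0.0052), Socs36E in cut P3/4 at 12 h (0.016 without cut replicate 3, 0.018 without uncut replicate 2 and 0.018 without uncut replicate 3, range -0.084 to 0.018), chinmo in cut A1/4 at 24 h (-0.010 with array weights and -0.053 without uncut replicate 3, range -0.053 to 0.33), and the differences between 24 and 12 h of upd (-0.45) and chinmo (-0.029) after quantile normalization. The counts as reported are 1660 (cut A1/4 12 h), 947 (cut P3/4 12 h), 1618 (cut A1/4 24 h), 1848 (cut P3/4 24 h), 2965 (culture A1/4 12 h), 3795 (culture P3/4 12 h), 6020 (culture A1/4 24 h), 4525 (culture P3/4 24 h), 134 (uncultured regions), 39 (piece difference 12 h), 23 (piece difference 24 h), 403 (time difference A1/4), 89 (time difference P3/4), 3100 (cut mean 12 h), 3340 (cut mean 24 h), 69 (time difference mean), 5161 (cut 24 h against uncultured), 571 (cultured regions 12 h) and 566 (cultured regions 24 h). After quantile normalization the counts were 2180 (cut P3/4 12 h), 1910 (culture A1/4 12 h), 3455 (culture A1/4 24 h), 32 (uncultured regions), 171 (time difference mean) and 1300 (cultured regions 12 h). With array weights the counts were 2589 (cut P3/4 12 h), 1866 (culture A1/4 12 h), 5823 (culture P3/4 12 h), 3962 (culture A1/4 24 h), 60 (uncultured regions), 143 (piece difference 12 h), 40 (piece difference 24 h), 380 (time difference P3/4), 4653 (cut mean 12 h), 151 (time difference mean) and 2041 (cultured regions 12 h). With robust empirical Bayes the counts were 20 (piece difference 12 h), 14 (piece difference 24 h) and 57 (time difference P3/4). At an unadjusted p under 0.001 the counts were 1023 (cut A1/4 12 h), 1035 (cut A1/4 24 h), 1158 (cut P3/4 24 h), 1675 (culture A1/4 12 h), 2494 (culture P3/4 12 h), 3437 (culture A1/4 24 h), 2873 (culture P3/4 24 h), 204 (uncultured regions), 123 (piece difference 12 h), 93 (piece difference 24 h), 186 (time difference P3/4), 1750 (cut mean 12 h), 2085 (cut mean 24 h), 159 (time difference mean) and 3091 (cut 24 h against uncultured). With at least a 2-fold change required the counts were 339 (cut A1/4 12 h), 107 (cut P3/4 12 h), 183 (cut A1/4 24 h), 324 (cut P3/4 24 h), 341 (culture A1/4 12 h), 703 (culture P3/4 12 h), 948 (culture A1/4 24 h), 779 (culture P3/4 24 h), 57 (uncultured regions), 136 (time difference A1/4), 177 (cut mean 12 h), 222 (cut mean 24 h), 12 (time difference mean), 606 (cut 24 h against uncultured), 93 (cultured regions 12 h) and 78 (cultured regions 24 h). Fitted on the compared groups alone the counts were 1127 (cut P3/4 24 h), 1498 (culture A1/4 12 h), 3361 (culture A1/4 24 h), 161 (piece difference 12 h), 263 (time difference A1/4) and 898 (cultured regions 12 h). With 1 probe set per named gene the counts were 1467 (cut P3/4 12 h), 2757 (culture A1/4 24 h), 2747 (culture P3/4 24 h), 135 (piece difference 12 h), 64 (piece difference 24 h), 202 (time difference P3/4), 1967 (cut mean 12 h), 2192 (cut mean 24 h), 121 (time difference mean), 2615 (cut 24 h against uncultured), 337 (cultured regions 12 h) and 337 (cultured regions 24 h). With an estimated correlation 2 pathway lists were called in the planned comparisons, against 71, and 0 in the added ones, against 30. Stricter or looser thresholds account by construction for the counts at other thresholds. For the scalings, weights, the robust fit, the compared groups and the named genes the cause was not tested. The share of rises crossed 50% in some settings. For cut A1/4 12 h it was 35.7%, but 51.6% with at least a 2-fold change. For cut P3/4 24 h it was 48.8%, but 52.8% at an unadjusted p under 0.001, 67.9% with at least a 2-fold change, 58.0% on the compared groups alone and 52.2% with named genes. For culture P3/4 12 h it was 51.7%, but 49.2% after quantile normalization and 49.8% with array weights. For culture A1/4 24 h it was 43.7%, but 50.0% after quantile normalization, 53.2% after median centring, 66.2% with at least a 2-fold change, 52.9% on the compared groups alone and 54.2% with named genes. For piece difference 12 h it was 51.3%, but 47.8% on the compared groups alone. For piece difference 24 h it was 56.5%, but 45.2% at an unadjusted p under 0.001, 36.8% on the compared groups alone and 39.1% with named genes. For cut mean 24 h it was 51.4%, but 46.8% after median centring and 48.7% with array weights. For cut 24 h against uncultured it was 50.6%, but 50.0% with the replicate block. For cultured regions 12 h it was 48.7%, but 50.2% with the replicate block, 51.6% after quantile normalization, 65.3% with array weights and 52.9% on the compared groups alone. Leaving out 1 array gave 839 to 1528 (cut A1/4 12 h), 393 to 875 (cut P3/4 12 h), 836 to 1576 (cut A1/4 24 h), 1055 to 2002 (cut P3/4 24 h), 2179 to 3643 (culture A1/4 12 h), 3053 to 3366 (culture P3/4 12 h), 5069 to 6226 (culture A1/4 24 h), 3516 to 4182 (culture P3/4 24 h), 66 to 306 (uncultured regions), 3 to 44 (piece difference 12 h), 2 to 103 (piece difference 24 h), 169 to 519 (time difference A1/4), 24 to 314 (time difference P3/4), 2316 to 3022 (cut mean 12 h), 2759 to 3393 (cut mean 24 h), 40 to 121 (time difference mean), 4305 to 5584 (cut 24 h against uncultured), 354 to 606 (cultured regions 12 h), 384 to 691 (cultured regions 24 h), 68 to 76 (planned list calls) and 25 to 31 (added list calls). For the piece difference 12 h the arrays that moved it were cut 12 h A1/4 replicate 1 (7), cut 12 h A1/4 replicate 3 (18), cut 12 h P3/4 replicate 2 (11), cut 12 h P3/4 replicate 3 (4), uncut 12 h A1/4 replicate 1 (24), uncut 12 h A1/4 replicate 3 (3) and uncut 12 h P3/4 replicate 3 (12). For the piece difference 24 h the arrays that moved it were cut 24 h A1/4 replicate 1 (2), cut 24 h A1/4 replicate 2 (4), cut 24 h A1/4 replicate 3 (41), cut 24 h P3/4 replicate 1 (49), cut 24 h P3/4 replicate 2 (3), cut 24 h P3/4 replicate 3 (9), uncut 24 h A1/4 replicate 1 (10), uncut 24 h A1/4 replicate 2 (13), uncut 24 h P3/4 replicate 1 (4), uncut 24 h P3/4 replicate 2 (103) and uncut 24 h P3/4 replicate 3 (6). For the time difference A1/4 the arrays that moved it were cut 12 h A1/4 replicate 3 (169), cut 24 h A1/4 replicate 1 (220), cut 24 h A1/4 replicate 2 (187), uncut 12 h A1/4 replicate 1 (178), uncut 24 h A1/4 replicate 1 (242) and uncut 24 h A1/4 replicate 2 (263). For the time difference P3/4 the arrays that moved it were cut 12 h P3/4 replicate 2 (40), cut 12 h P3/4 replicate 3 (24), cut 24 h P3/4 replicate 2 (52), cut 24 h P3/4 replicate 3 (55), uncut 12 h P3/4 replicate 1 (146), uncut 12 h P3/4 replicate 3 (42), uncut 24 h P3/4 replicate 1 (30), uncut 24 h P3/4 replicate 2 (314) and uncut 24 h P3/4 replicate 3 (36). For the time difference in P3/4 the share of higher calls was 65.2% after quantile normalization in place of 82.0%. With the replicate number as a block the counts were 1761 (cut A1/4 12 h), 1053 (cut P3/4 12 h), 1742 (cut A1/4 24 h), 2024 (cut P3/4 24 h), 3092 (culture A1/4 12 h), 3904 (culture P3/4 12 h), 6109 (culture A1/4 24 h), 4658 (culture P3/4 24 h), 128 (uncultured regions), 43 (piece difference 12 h), 21 (piece difference 24 h), 455 (time difference A1/4), 101 (time difference P3/4), 3231 (cut mean 12 h), 3434 (cut mean 24 h), 74 (time difference mean), 5296 (cut 24 h against uncultured), 630 (cultured regions 12 h), 599 (cultured regions 24 h), 69 (planned list calls) and 28 (added list calls), and no count moved by over 1.5 times. Same-numbered replicates did not deviate together in every pair (the lowest correlation was -0.19), and in 0 of 9 comparisons did all pairs exceed 0.1, so they were not taken as pairs. A filter on dim probe sets, a variance trend and the choice of probe sets by highest mean were not run, since the centred values hold no signal level, and signal over background is unknown.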

Other observations

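Of the tests in this part, those of a smaller share of disc cells, of a return to the uncultured state, of exchanged region labels and of the splits for averaged comparisons were chosen after the result was seen. Members of further lists were counted in culture and in cut discs. Of 12 cuticle and chitin genes, 9 rose and 2 fell in A1/4 after 24 h of culture, 8 and 1 in P3/4 at 24 h and 6 and 1 at 12 h (9 and 2, 8 and 2, and 8 and 2 adjusted over the list alone), and in cut against uncut discs at 24 h 0 rose and 4 fell (1 and 5 adjusted over the list alone), among them Cpr100A (-2.07) and Lcp65Ad (-1.69). Of 9 genes of basement membrane and matrix remodelling, 3 rose and 4 fell in cut discs at 12 h, with Tig (1.06) and Mmp2 (1.05) up and the collagen IV genes vkg (-0.50) and Col4a1 (-0.48) down, and 3 and 0 at 24 h (the same counts adjusted over the list alone at both times). Of 9 genes of wound closure and actomyosin, 1 rose and 2 fell at 12 h and 5 and 2 at 24 h, with the receptor gene Pvr at 0.82, Act5C at 0.57 and grh at -0.36 (1 and 2, and 5 and 2, adjusted over the list alone). All 3 named Dpp genes, of 13 listed, fell in cut discs at both times, as did all 3 named EGFR and Ras genes, of 15 listed. At 24 h bi was at -0.90 and ru at -0.83 (3 of 3 adjusted over the list alone). The smallest of these falls were lost when 1 array was left out, Mad at 12 h with any 1 of 4 arrays (-0.28 to -0.24) and shn and Krn at 24 h with any 1 of 8 (-0.19 to -0.16) and 3 arrays (-0.27 to -0.25), and bi at 12 h was lost after quantile normalization. Of 2 Polycomb genes both fell at both times, with Su(z)2 at -0.58 at 24 h, and boi, the 1 named Hedgehog gene, fell by 0.41 and 0.26, a call that was lost at 24 h without any 1 of 5 arrays (-0.25 to -0.21). Of 5 Hippo pathway genes 1 fell at each time (4 and 3 adjusted over the list alone), of 4 selector genes of other discs 2 and 3 fell (2 and 3), and of 3 heat shock genes 2 fell at 12 h and 1 rose at 24 h (2 and 1). Of 6 mitosis genes 0 rose and 1 fell at 12 h and 2 rose and 2 fell at 24 h (1 and 2, and 2 and 2, adjusted over the list alone). The fall at 12 h and 1 fall at 24 h were those of fzy (-0.47 and -0.43), whose other probe set gave 0.22 (not called) and 0.53 (called), so no direction can be given for it. The rise of aurB at 24 h was lost without cut A1/4 replicate 2 (0.31), cut P3/4 replicate 1 (0.29) or uncut A1/4 replicate 2 (0.26). Of the markers of larval fat body 1 of 2 rose at both times, of muscle 1 of 3 rose, and of trachea 1 of 3 fell at both times, and adjusted over the list alone 1 fat body marker rose and 1 fell, with the same counts for muscle and trachea. The lists of adult midgut enzymes and dosage compensation RNAs had 0 named members. None of the lists in this paragraph was called by camera in the cut comparisons averaged over regions.

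Genes that fell in culture were often higher in cut than in uncut cultured discs, tested on comparisons that share no array. Of 896 probe sets lower after 12 h of culture in P3/4 and called in the cut comparison at 24 h, 808 (90.2%) were higher in cut discs, against 168 that fell and rose by chance in independent lists. Of 791 that were higher in culture, 611 (77.2%) were lower in cut discs. For culture of P3/4 for 24 h and the cut comparison at 12 h the shares were 87.6% (509 of 581) and 91.7% (1094 of 1193), with r = -0.36 across all probe sets, which are not independent replicates. With culture of A1/4 for 24 h they were 81.1% and 89.9%. A candidate explanation is a partial return of cut discs towards the uncultured state, and weaker culture changes in the selected GFP-positive cells stay open, untested.

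The fall of oxidative phosphorylation genes in culture could reflect RNA quality or scaling. With the actin 3′ to 5′ difference as a covariate the median in A1/4 at 24 h was -0.74 (-0.86 without it, SD 0.27 over 51 genes), and 36 of 51 stayed called. After quantile normalization it was -0.71. The median thus stayed negative in both checks, but neither decides the cause. The covariate differed between the compared groups along with culture, and its slope came from differences between arrays within groups. Quantile normalization was run on centred values, which hold no signal level. RNA quality, scaling and a change of the tissue in culture stay open, the last untested.

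Immune genes were higher in cut discs together with haemocyte markers. Over the 30 arrays, deviations of the 2 list means from their group means correlated with r = 0.32 (permutation p = 0.202) and rho = 0.41 (permutation p = 0.0819), in 1 relation tested, and r = 0.22 without the 2 farthest arrays, so blood cells in the pieces may contribute and the arrays do not decide it. Of the 5 markers, all chosen on these samples through the authors' tables, Hml, eater, NimC1 and Sr-CI were 1.30, 1.42, 1.21 and 1.44 higher at 24 h, and the isolation of GFP-positive cells would remove unlabelled haemocytes. The myoblast markers had a median of -0.42 at 24 h, but the same isolation would remove unlabelled myoblasts, so this value does not decide whether the share of disc cells was smaller. That, haemocytes and an immune response of the disc cells stay open.

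Exchanged region labels between the cut groups were checked with 134 probe sets called between the uncultured regions, of which 83.6% had the same sign at 12 h and 79.9% at 24 h in the comparisons averaged over cut and uncut discs. Of those called in both, 61 of 63 and 54 of 58 had the same sign. These shares decide nothing, since after the centring a region difference with the labels as given has the same values in all 10 groups as a cut response that differs between the pieces with exchanged labels. As labelled, 0 of 3 centred sets hold a single region, and with the cut labels exchanged all 3 would. An exchange therefore stays open, and the cut responses averaged over both regions and the culture comparisons of uncut discs do not depend on it.

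The numbers of calls were compared with other splits of the same arrays. For the 9 comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05. The real and highest other counts were 1660 and 0, 947 and 2, 1618 and 3, and 1848 and 63 for cut discs (A1/4 and P3/4 at 12 h, then at 24 h), 2965 and 5, 3795 and 1, 6020 and 1112, and 4525 and 3 for culture in the same order, and 134 and 4 for the uncultured regions. For the comparisons averaged over regions or treatments, the real split alone of the 100 reached its count. These splits exchange arrays between separately centred sets, and the set means cancel in the real split but not in splits that mix the sets. The arrays were therefore not exchangeable, and these shares do not exclude a chance assignment. The real and highest other counts were 3100 and 894 for cut discs at 12 h, 3340 and 1177 at 24 h, 5161 and 3688 for cut at 24 h against uncultured discs, 571 and 292 for the regions at 12 h and 566 and 184 at 24 h.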
